A study of Mus musculus with 49 samples.

How the data were processed

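Gene expression was measured by RNA sequencing in 49 libraries from 6 tumor-bearing HuHER2 mice, a strain that carries human HER2, a growth factor receptor gene of breast cancer, as a transgene. Per the labels, 3 mice received PBS and 3 received BP, an iron oxide nanoparticle preparation named there only by this code, as 1 intravenous injection of 5 mg Fe per mouse. Organs were taken 7 days later per the series' design text, while a treatment protocol label names 31 days. From each mouse the tumor, lung, lymph node, spleen, liver and bone marrow were sequenced as whole (bulk) tissue, which gave 36 libraries. A further part of each organ except lung from BP mice was digested to single cells, and the cells that held nanoparticles were separated with a magnet. These nanoparticle-associated cells gave 13 libraries, 3 each from tumor, spleen, liver and bone marrow and 1 from lymph node (BP mouse 2). The samples formed 17 groups, of which 16 held 3 libraries, 1 per mouse. Lung had no nanoparticle-associated libraries, and a NanoString experiment named in the design text was not analysed here.

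The deposited values were expected counts (estimated counts) per gene as deposited, the unit written by RSEM, which the authors name in their processing notes. Those notes name FastQC 0.11.9, cutadapt 3.5, STAR 2.7.9a, RSEM 1.3.1 and the genome build mm10, without roles or settings. The library kit's strand setting and the annotation release were not given in the sources used here. RSEM divides reads that match several genes by estimation, so 4.64 to 7.92% of all values per library, zeros included, were not whole. Close copies of a gene (Hspa1a and Hspa1b, the hemoglobin genes, the Saa genes) and genes that overlap another gene (Exosc6, Trim69) therefore have uncertain counts. The table held 55487 genes, of which 55141 matched a symbol and 55227 a position in the GENCODE M21 annotation of GRCm38 (the assembly behind mm10). Coordinates below come from that annotation, count from 1 and span the whole gene.

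Library totals ran from 9362264 to 19734849 expected counts. A gene at 0 counts in a library may hold up to 3 counts, which is 0.152 to 0.32 CPM (counts scaled to a common library total). Intervals and floors cover counting error alone, since the reads carried no molecular identifiers that the sources name. Replicate libraries differed by more than sampling noise, with a chi-square of at least 9.17 per degree of freedom in each pair, so none was counted as a duplicate.

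Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment, adjusted p under 0.05, two-sided). Each organ was fitted on its own 6 libraries: BP against PBS bulk tissue in 6 organs, and nanoparticle-associated cells against the BP bulk tissue in 4 organs. Adjusted p-values of genes below are from this test unless another is named. CPM values carry the TMM scaling of their fit and are given as mean ± SD (n = 3), and log2 fold changes as estimate ± standard error. Whether an organ's change differed from the mean change of the other organs was tested as an interaction in 1 fit of the 36 bulk libraries and in 1 fit of the 24 libraries of the 4 organs. Organs of 1 mouse are not independent, and these fits share 1 estimate of the spread per gene over organs.

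Before the data were examined, 33 gene lists were fixed from textbook knowledge. Those of immune cells were macrophage, tissue-resident macrophage of liver and spleen, monocyte, classical and alternative macrophage activation, neutrophil, T cell, natural killer and cytotoxic lymphocyte, regulatory T cell and checkpoint, B cell, plasma cell, dendritic cell, and mast cell with basophil and eosinophil. Those of processes were iron handling, antioxidant and ferroptosis, type I interferon response, antigen presentation and interferon gamma response, chemokine and cytokine, complement and acute phase, lysosome and phagocytosis, cell cycle, lung premetastatic niche, and dissociation response (immediate early and heat shock genes known to rise during tissue digestion). Those of other cells were erythroid, megakaryocyte and platelet, mammary epithelium, mesenchymal and extracellular matrix, endothelium and angiogenesis, lung epithelium, hepatocyte, adipocyte, skeletal muscle and exocrine pancreas. Each list with at least 5 tested members was compared with all other genes by camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, and list p-values below are camera's. The same test with the correlation estimated from the data was an alternative. Some genes stand in several lists, so the lists are not independent.

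The genes named were also fixed by rule before the data were examined: per direction the 6 genes with the largest change among those past the threshold whose groups did not overlap, with a mean log2 CPM of at least 2 and an approved-style symbol, all calls where there were under 6, and members of the lists. The list members given as examples were picked after their values were seen.

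The alternatives fixed before the data were examined were DESeq2's size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), leaving out genes with over 1% of the counts, the replicate number as a block (replicate block, through limma voom in the fits across organs), the spread estimated over 48 libraries, and leaving out each library. Further alternatives were chosen after seeing the data: fits without the libraries that hold unusual shares of liver, lung, fat or mammary transcripts, without mitochondrial genes in liver, with list tests after leaving out each library, and interaction fits with organ-specific weights and the mouse as a block in limma voom, with limma voom without a block, without each mouse or, for lists, with an estimated correlation. For nanoparticle-associated cells against bulk tissue the labels give both libraries of a number to the same animal, so the numbers pair the samples. The correlations of their deviations from the group means over pairs 1, 2 and 3 were -0.054, 0.392 and 0.282 in tumor, 0.376, 0.615 and -0.185 in spleen, 0.129, 0.067 and 0.014 in liver, and -0.076, 0.404 and -0.074 in bone marrow. The main test did not use this pairing, while the replicate block did. The main test gave 1321 genes in tumor, 6340 in spleen, 9907 in liver and 1044 in bone marrow. With the block the counts were 625, 8122, 9754 and 2719 in the same order. BP and PBS mice of the same number are different animals and were not paired.

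The tests within single organs were first run on simulated counts drawn from the real means, spread and depths. These covered the 12740 to 15714 genes tested per comparison, with 200 changed genes per draw and 5 draws. For BP against PBS the share of genes with a 4-fold change that was recovered was 14.3% in tumor, 48% in lymph node, 79.3% in spleen, 81.7% in lung, 89% in bone marrow and 93.7% in liver. At a 2-fold change it was 0, 2, 19, 19, 66.2 and 61.8% in the same order. For nanoparticle-associated cells it was 41.3% in tumor, 70.7% in spleen, 91.3% in liver and 88.7% in bone marrow at 4-fold. Draws without change gave 0 to 3 calls, and with 200 genes changed 3.8 to 9.4% of calls over the draws were false. The interaction tests were simulated in a single draw, over 18613 genes for BP and 17281 for nanoparticle-associated cells. With 200 genes changed in bone marrow alone, the BP interaction test called 91 genes there, of which 90 were among those changed. It called 0 to 2 in the other organs. All organs had the same spread per gene in this simulation, so it cannot show false calls that come from unequal spread. The same simulation of nanoparticle-associated cells gave 91 calls in bone marrow (89 among those changed), 25 in spleen, 13 in liver and 10 in tumor.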

Results

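The data consist of 49 libraries from 6 mice that bore HER2-driven mammary tumors. Bulk tumor, lung, lymph node, spleen, liver and bone marrow were each represented by 3 BP mice and 3 PBS mice. Nanoparticle-associated cells were represented by 3 libraries each for tumor, spleen, liver and bone marrow and by 1 for lymph node. Between 17214 and 23241 genes were detected per library. Mitochondrial transcripts held 48.2 to 57.2% of the counts in nanoparticle-associated liver cells, against 5.67 to 7.06% in bulk liver of the same mice. Libraries of 1 group came from different mice, so the spread between them holds both animal and technical differences.

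Transcripts of abundant organ-specific genes were present at low levels in libraries of other organs. Alb, which encodes serum albumin of hepatocytes, stood at a median of 60420 CPM of the library total in the 6 bulk livers and at a median of 228.8 CPM (1.44 to 501.4) in the 34 libraries of tumor, lymph node, spleen and bone marrow, which is 0.379% of the liver median. Of these 34 libraries, 18 held both Alb and Sftpc, the surfactant protein C gene of lung epithelium. In 8 the lung transcript was near 0 while Alb was present: bone marrow, spleen and tumor of PBS mouse 1, and nanoparticle-associated cells of mice 2 and 3 from bone marrow and spleen and of mouse 2 from lymph node. In another 8 lung transcripts were high relative to Alb: bone marrow, spleen, tumor and lymph node of BP mouse 3, lymph node of BP mouse 2, and nanoparticle-associated cells of mouse 1 from bone marrow, spleen and tumor. These sets of libraries were defined from the data and cross the study's groups unevenly. Single libraries also held transcripts typical of other tissues. The tumor of BP mouse 1 held the adipocyte genes Adipoq and Ucp1 at 868.6 and 878.7 CPM with 19.5% mitochondrial counts, and the tumor of BP mouse 2 held Acta1 of skeletal muscle at 1409 CPM. The lymph node of PBS mouse 2 held Ucp1 at 1421 CPM with 28.6% mitochondrial counts. The lung of PBS mouse 2 held the milk gene Lalba at 142.3 CPM, and the lung of PBS mouse 1 held the immediate early gene Fos at 248.6 CPM.

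**Figure D1:**
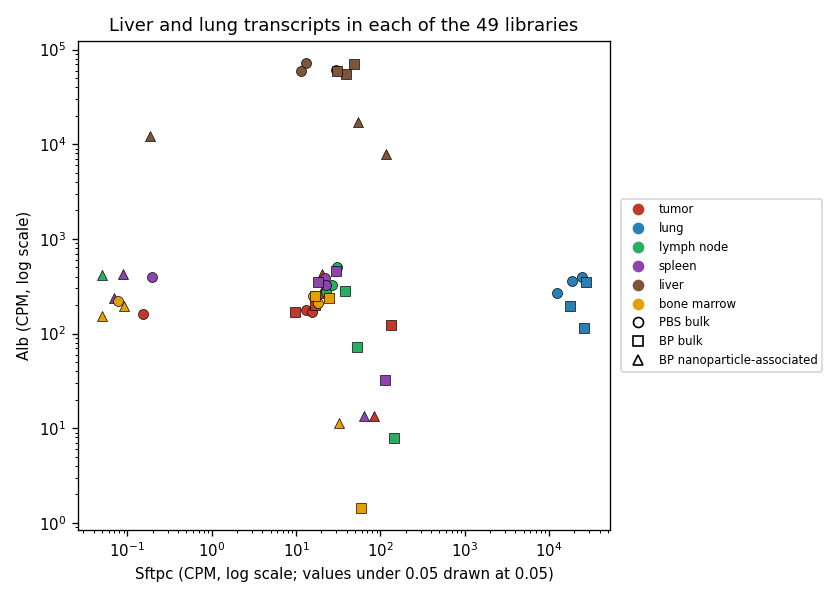
Alb and Sftpc in CPM of the library total for each of the 49 libraries, on log axes, colored by organ, with the symbol giving the treatment and cell fraction. Bulk livers lie between 55770 and 72540 CPM of Alb, and libraries of tumor, lymph node, spleen and bone marrow lie between 1.44 and 501.4 CPM, with 8 of them near 0 for Sftpc.

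The first question was what a single dose of BP had changed in each whole organ. In liver, 3 genes expressed in macrophages rose in BP mice. Lyz2 (ENSMUSG00000069516; chromosome 10, 117277331 to 117282321), which encodes lysozyme of myeloid cells, rose from 96.3 ± 5.09 to 264 ± 8.855 CPM (log2 fold change 1.46 ± 0.095, adjusted p = 0.00109). Gpnmb (ENSMUSG00000029816; chromosome 6, 49036546 to 49070929), a membrane glycoprotein of lysosome-rich macrophages, rose from 0.183 ± 0.0994 to 7.29 ± 3.16 CPM (log2 fold change 5.27 ± 0.495, adjusted p = 0.013). Vcam1 (ENSMUSG00000027962; chromosome 3, 116109949 to 116129688), a leukocyte adhesion molecule of endothelium and liver macrophages, rose from 17.1 ± 1.845 to 46.0 ± 9.565 CPM (log2 fold change 1.42 ± 0.16, adjusted p = 0.0432). No gene fell in this test of 12740 genes by edgeR. An unadjusted p under 0.05 was found for 454, where chance gives 637.

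The macrophage list was higher in BP livers (adjusted p = 1.18e-16, 0.137 with an estimated correlation). Of its 22 members 18 were higher, 1 rose over all genes and 5 did when adjusted over the list alone. The lysosomal glycoprotein Cd68 went from 12.99 ± 1.42 to 26.35 ± 2.89 CPM (adjusted p = 0.0673), the lipid receptor Trem2 from 0.384 ± 0.3085 to 3.57 ± 0.993 CPM (adjusted p = 0.0932) and the complement gene C1qa from 76.7 ± 9.29 to 104.5 ± 9.68 CPM (adjusted p = 0.938). The resident macrophage list was higher as well (adjusted p = 8.7e-06, 0.357 with an estimated correlation), with 1 of 18 members risen and the scavenger receptor Marco at 24.7 ± 9.91 and 64.6 ± 8.57 CPM in PBS and BP mice (adjusted p = 0.2). In the lysosome and phagocytosis list (adjusted p = 7.91e-07, 0.106 with an estimated correlation) 1 of 29 members rose over all genes, which was Gpnmb, and 5 did when adjusted over the list alone. The tetraspanin Cd63 went from 4.87 ± 1.26 to 13.7 ± 1.84 CPM (adjusted p = 0.081) and the protease Ctsd from 571.5 ± 36.9 to 789.9 ± 18.1 CPM (adjusted p = 0.417). The adipocyte list was higher (adjusted p = 0.000246, 0.137 with an estimated correlation), with 0 of 10 members past the threshold and 3 when adjusted over the list alone. Its member Lpl, lipoprotein lipase, which macrophages also express, went from 12.2 ± 1.23 to 33.8 ± 8.11 CPM (adjusted p = 0.0575).

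Mesenchymal (adjusted p = 4.21e-05, median log2 fold change 0.22) and dendritic cell genes (adjusted p = 0.00275, median 0.17) were also higher in BP livers, with adjusted p = 0.253 and 0.311 with an estimated correlation. Complement and acute phase genes were lower (adjusted p = 5.93e-05, 23 of 27 members), as were erythroid genes (adjusted p = 0.0294), with adjusted p = 0.598 and 0.384 with an estimated correlation. Lung epithelium genes were higher (adjusted p = 0.000222, 0.311 with an estimated correlation), and Sftpc stood at 18.4 ± 9.48 CPM in PBS and 38.6 ± 10.5 CPM in BP livers. The lung premetastatic niche list was called higher (adjusted p = 0.0347, 0.357 with an estimated correlation) with a mean log2 fold change of 0.13 and a median of -0.07. Iron handling was not called (adjusted p = 0.925), and Hmox1, the heme oxygenase gene, stood at 51.9 ± 5.31 and 64.0 ± 17.6 CPM (adjusted p = 0.999).

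In liver DESeq2 called 37 genes (32 higher), and the groups did not overlap in CPM for 1065 genes, or 8.4%, where chance gives 10%. The count was 8 without BP mouse 3, 9 without PBS mouse 3, and 1 without PBS mouse 1 or PBS mouse 2. Lyz2 was called with each library left out (adjusted p up to 0.0284), Gpnmb lost its call without PBS mouse 1 or 2 (up to 0.132) and Vcam1 without BP mouse 1 or 2 or PBS mouse 1 or 2 (up to 0.298). With the spread estimated over 48 libraries of all organs all 3 calls were lost (adjusted p = 1, 0.0808 and 0.503), against 6.89e-33 to 0.0284 for Lyz2 over its other alternatives. Of the 10 list calls, 2 were lost without BP mouse 1 (adjusted p = 0.185 to 0.564), 2 without BP mouse 2 (0.0851 to 0.101), 2 without PBS mouse 2 (0.0788 to 0.451) and 1 without PBS mouse 3 (0.759). The macrophage, resident macrophage, lysosome, mesenchymal, lung epithelium and adipocyte lists were called with each library left out.

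**Figure D2:**
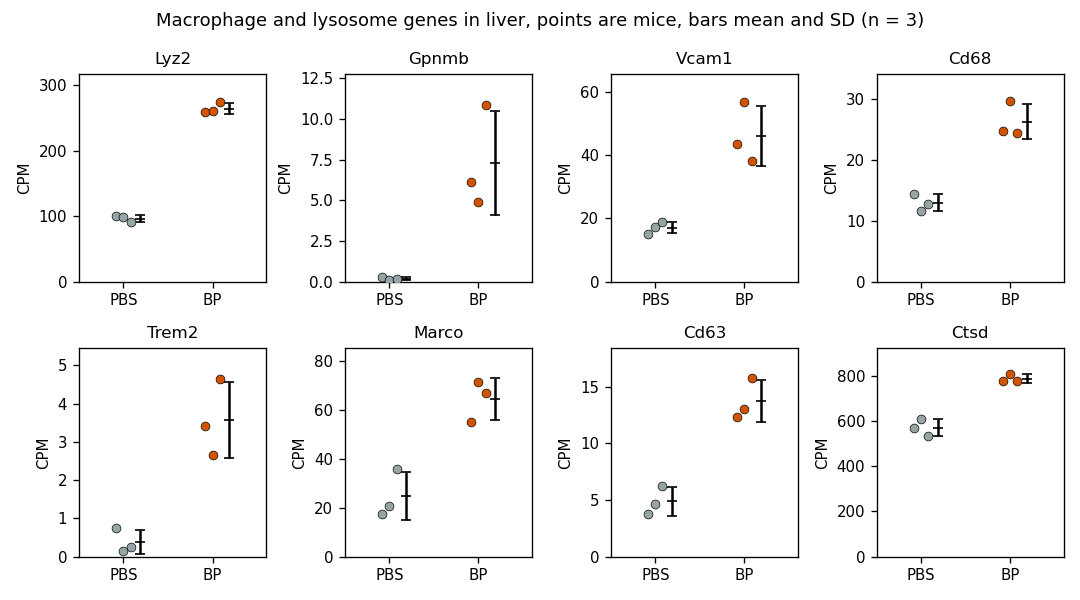
CPM of 8 macrophage and lysosome genes in bulk liver of PBS and BP mice, with 1 point per mouse and bars for mean and SD (n = 3). The BP mice lie above all PBS mice for each gene, and Lyz2, Gpnmb and Vcam1 passed the adjusted threshold while the other 5 did not.

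In spleen, neutrophil and lysosome genes were higher in BP mice as groups, while no single gene passed the test. None of the 15 list calls in spleen held with an estimated correlation (adjusted p = 0.688 each). All 24 neutrophil genes were higher (median log2 fold change 0.55, adjusted p = 2.23e-11), among them the granule genes Elane at 19.4 ± 5.35 and 34.7 ± 18.75 CPM in PBS and BP mice and Ngp at 161 ± 70.4 and 268 ± 134 CPM. Of 30 lysosome genes 27 were higher (median 0.21, adjusted p = 1.08e-08). Gpnmb stood at 12.2 ± 1.64 and 30.3 ± 18.4 CPM. Macrophage (adjusted p = 2.15e-08), monocyte (5.09e-05), resident macrophage (0.0307), mast cell (0.00228), plasma cell (0.0457), interferon (0.0257), premetastatic niche (0.00903) and adipocyte lists (3.96e-11) were higher too, the last with Adipoq at 2.60 ± 1.985 and 5.23 ± 1.08 CPM. T cell (0.00231), complement (0.00231) and mammary lists (0.00276) were lower. Hepatocyte genes were lower (adjusted p = 3.96e-11) and lung epithelium genes higher (1.72e-05). Sftpc stood at 16.35 ± 14.0 CPM in PBS and 53.1 ± 49.2 CPM in BP spleens. By edgeR 0 of 15195 genes passed and 108 had an unadjusted p under 0.05, where chance gives 760. DESeq2 called 0, and 681 genes (4.5%) did not overlap between groups, where chance gives 10%. The neutrophil, lysosome and adipocyte calls held with each library left out, while 7 of the 15 were lost without BP mouse 1 (adjusted p = 0.129 to 0.964), 3 without BP mouse 2 (0.0558 to 0.778), 4 without BP mouse 3 (0.0727 to 0.697), 9 without PBS mouse 1 (0.0552 to 0.958), 5 without PBS mouse 2 (0.0797 to 0.321) and 3 without PBS mouse 3 (0.0509 to 0.132). Directions turned without BP mouse 1 for T cell, plasma cell, premetastatic niche and resident macrophage genes, the last also without PBS mouse 1, and without BP mouse 3 for complement and hepatocyte genes.

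In tumor, genes of fat, vessels and stroma were higher in BP mice and cell cycle genes lower as groups, with no single gene past the threshold. None of the 15 list calls held with an estimated correlation (adjusted p = 0.532 to 0.732), and the cell cycle list turned without BP mouse 1 (0.661). All 20 adipocyte genes were higher (median log2 fold change 5.53, adjusted p = 3.87e-19) and 16 rose when adjusted over the list alone, with Adipoq at 7.45 ± 7.52 and 425 ± 607 CPM in PBS and BP tumors and the fat regulator Pparg at 0.862 ± 0.498 and 39.2 ± 58.0 CPM. Of 24 endothelial genes 23 were higher (median 1.80, adjusted p = 6.36e-14), with Vwf, the von Willebrand factor gene, at 2.21 ± 0.946 and 19.7 ± 19.9 CPM and Lyve1 of lymphatic vessels at 0.637 ± 0.6715 and 9.09 ± 7.41 CPM. Mesenchymal (1.22e-06), mast cell (7.89e-06), B cell (5.19e-05), alternative macrophage activation (5.68e-05), chemokine (0.00109), dendritic cell (0.00118), macrophage (0.00246), lung epithelium (0.00567), skeletal muscle (0.0134), complement (0.015), erythroid (0.0422) and resident macrophage genes (0.0439) were higher as lists. Of 5 tested muscle genes 3 rose when adjusted over the list alone. Cell cycle genes were lower in 30 of 32 cases (median -0.50, adjusted p = 7.97e-05). Top2a stood at 149 ± 61.1 and 104.8 ± 72.1 CPM. The tumors of BP mice 1 and 2 were those rich in fat and in muscle transcripts, in that order, and without the latter the muscle genes were lower: Acta1, BP against PBS, tumor BP 2 left out, had a log2 fold change of -1.30 in place of 8.475. The erythroid list turned without it as well (0.577).

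Hmox1 went the other way in tumor, from 138 ± 23.99 to 29.9 ± 8.69 CPM (log2 fold change -2.21 ± 0.30, unadjusted p = 0.000149, adjusted p = 0.797). It was the single member of the iron handling list that fell when adjusted over the list alone, and DESeq2 called it (adjusted p = 1.73e-06, against 6.48e-05 to 0.999 over its other alternatives). The iron list itself was not called in tumor (adjusted p = 0.559). Over all genes edgeR called 0 of 14535 in tumor, with 867 at an unadjusted p under 0.05, where chance gives 727. DESeq2 called 138 (128 higher) and the fit with the spread over 48 libraries 1482. Groups did not overlap for 1570 genes (10.8%), where chance gives 10%. The biological coefficient of variation was 0.513 in tumor, against 0.15 to 0.381 in the other organs. Of the 15 list calls 3 were lost without BP mouse 1 (adjusted p = 0.597 to 0.661), 4 without BP mouse 2 (0.132 to 0.577), 1 without BP mouse 3 (0.247), 4 without PBS mouse 1 (0.0636 to 0.179), 4 without PBS mouse 2 (0.102 to 0.854) and 2 without PBS mouse 3 (0.0834 to 0.196). Adipocyte, endothelial, mesenchymal, mast cell, B cell, dendritic cell and alternative macrophage calls held with each library left out.

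In lung, lysosome and chemokine genes were higher in BP mice and hepatocyte genes lower as groups. With an estimated correlation none of the 14 list calls held (adjusted p = 0.748 to 0.825). Of 27 hepatocyte genes 25 were lower (median log2 fold change -0.64, adjusted p = 1.23e-17), such as Cyp2e1 at 41.0 ± 12.1 and 22.5 ± 9.65 CPM in PBS and BP lungs. Of 30 lysosome genes 27 were higher (median 0.17, adjusted p = 8.58e-06). The protease Ctsk stood at 45.8 ± 17.35 and 58.6 ± 14.95 CPM. Chemokine (4.31e-05), macrophage (0.00082), natural killer (0.00082), lung epithelium (0.00167), plasma cell (0.00546), classical macrophage activation (0.00626), neutrophil (0.0293) and interferon genes (0.044) were higher as lists, the first with Ccl8 at 2.01 ± 0.9475 and 3.40 ± 1.24 CPM. Complement (7.53e-07), mammary (0.00228), platelet (0.0045) and mesenchymal genes (0.0413) were lower. The mammary list held the milk genes Lalba at 54.6 ± 90.4 and 0.757 ± 0.107 CPM and Csn3 at 156 ± 225 and 19.7 ± 2.265 CPM, whose PBS means rest on the lung of PBS mouse 2. The premetastatic niche list, which holds genes known to prepare lung for tumor cells, was not called (adjusted p = 0.571, median -0.06). By edgeR 0 of 15714 genes passed (1 without PBS mouse 1) and 137 had an unadjusted p under 0.05 (786 by chance). DESeq2 called 0, and 694 genes (4.4%, 10% by chance) did not overlap. The hepatocyte call alone held with each library left out, as 10 were lost or turned without PBS mouse 1 (adjusted p = 0.0169 to 0.972), 6 without BP mouse 2 (0.122 to 0.726), 5 without PBS mouse 2 (0.0867 to 0.721), 3 without BP mouse 1 (0.063 to 0.356), 2 without BP mouse 3 (0.0895) and 1 without PBS mouse 3 (0.242). Without PBS mouse 1 macrophage, neutrophil (0.0435), natural killer (0.0169), plasma cell, interferon (also without BP mouse 2) and mesenchymal genes turned.

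In lymph node, interferon, antigen presentation, B cell and cell cycle genes were higher in BP mice as groups and fat, liver and stromal genes lower, with no single gene past the threshold. The 24 list calls were all lost with an estimated correlation (adjusted p = 0.384 to 0.606). Of 31 interferon response genes 29 were higher (median log2 fold change 1.08, adjusted p = 1.06e-14). The regulator Irf7 stood at 22.0 ± 0.925 and 64.7 ± 41.5 CPM and Isg15 at 4.94 ± 1.62 and 17.2 ± 10.99 CPM in PBS and BP mice. All 27 antigen presentation genes (median 0.59, adjusted p = 7.54e-12) and all 32 cell cycle genes (median 0.59, adjusted p = 4.03e-11) were higher. Of 17 B cell genes 16 were higher (adjusted p = 1.46e-11) and 1 rose when adjusted over the list alone, the survival receptor gene Tnfrsf13c at 43.9 ± 3.225 and 78.7 ± 10.7 CPM. Lists of checkpoint (9.85e-08), natural killer (9.85e-08), plasma cell (1.8e-06), lung epithelium (1.13e-06), dendritic cell (4.15e-05), classical macrophage activation (4.15e-05), chemokine (0.0022), macrophage (0.00316), T cell (0.00428), neutrophil (0.0124), mast cell (0.0142), dissociation (0.0144) and muscle genes (0.0449) were higher. The mast cell gene Tpsab1, at 1.49 ± 0.417 and 5.24 ± 1.28 CPM, was the other gene that rose when adjusted over its list alone. Hepatocyte (6.34e-19), complement (7.54e-12), adipocyte (2.16e-10), mammary (4.98e-08), mesenchymal (1.07e-05), iron handling (0.00633) and antioxidant genes (0.00769) were lower.

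Fat and liver transcripts moved with these lymph node groups. The brown fat gene Ucp1 stood at 859.7 ± 1062 CPM in PBS and 48.3 ± 15.7 CPM in BP mice, and Apoa1 of hepatocytes at 41.6 ± 42.05 and 7.01 ± 6.69 CPM. By edgeR 0 of 15341 genes passed and 554 had an unadjusted p under 0.05, where chance gives 767. DESeq2 called 11, and 1045 genes (6.8%) did not overlap, where chance gives 10%. Leaving out BP mice 2 and 3, whose nodes held more lung transcripts, a fit chosen after seeing the data, gave 46 calls, all higher in the remaining BP mouse. Of the list calls 4 were lost without BP mouse 1 (adjusted p = 0.15 to 0.476), 5 without BP mouse 2 (0.172 to 0.562), 4 without BP mouse 3 (up to 0.295), 2 without PBS mouse 1 (0.101 to 0.324), 7 without PBS mouse 2 (0.067 to 0.13) and 4 without PBS mouse 3 (0.0897 to 0.323), and the other 14 held. T cell genes turned without BP mouse 2 (0.274).

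In bone marrow, cell cycle, erythroid and interferon genes were higher in BP mice as groups and stromal, B cell and antigen presentation genes lower, by small amounts and with no single gene past the threshold. The 15 list calls were all lost with an estimated correlation (adjusted p = 0.533 to 0.711). Without single libraries B cell (0.00967 without BP mouse 2, 0.344 without PBS mouse 2), erythroid (0.446 without BP mouse 3), antigen presentation (0.837 without PBS mouse 3) and neutrophil genes (0.584 without PBS mouse 1) turned. Of 32 cell cycle genes 30 were higher (median log2 fold change 0.07, adjusted p = 0.00067), as were 24 of 27 erythroid genes (median 0.11, adjusted p = 0.00515) and 24 of 29 interferon genes (median 0.19, adjusted p = 0.000171), such as Irf7 at 21.9 ± 1.59 and 27.02 ± 2.93 CPM in PBS and BP mice. Mesenchymal genes were lower (adjusted p = 1.36e-06, median -0.27). The collagen gene Col1a1 stood at 39.9 ± 33.05 and 17.7 ± 14.3 CPM. Antigen presentation (0.00067), dendritic cell (0.000761), mammary (0.00192), neutrophil (0.0037), B cell (0.00802) and alternative macrophage activation genes (0.00946) were lower too, with the interferon-producing dendritic cell gene Siglech at 47.9 ± 11.1 and 35.7 ± 1.92 CPM. Hepatocyte (1.46e-14) and complement genes (3.33e-08) were lower and lung epithelium genes (0.0197) higher, with Cyp2e1 at 23.0 ± 1.77 and 11.3 ± 9.80 CPM and Sftpc at 11.4 ± 9.92 and 35.1 ± 25.85 CPM. Skeletal muscle (3.57e-07, median 1.20) and mast cell lists (0.00946) were higher. The monocyte list was not called (adjusted p = 0.661), and its member Ace rose when adjusted over the list alone, from 14.0 ± 0.848 to 21.8 ± 0.923 CPM. By edgeR 0 of 13969 genes passed and 184 had an unadjusted p under 0.05, where chance gives 698. DESeq2 called 4, and 827 genes (5.9%) did not overlap, where chance gives 10%. Without BP mouse 3 or PBS mouse 3 the edgeR count was 1. Of the list calls 8 were lost or turned without BP mouse 2 (adjusted p = 0.00967 to 0.58), 7 without PBS mouse 1 (0.0609 to 0.674), 4 without BP mouse 3 (0.105 to 0.489), 3 without PBS mouse 3 (0.074 to 0.837), 2 without PBS mouse 2 (0.2 to 0.344) and 1 without BP mouse 1 (0.0571), and the complement, mesenchymal and muscle calls held.

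**Figure D3:**
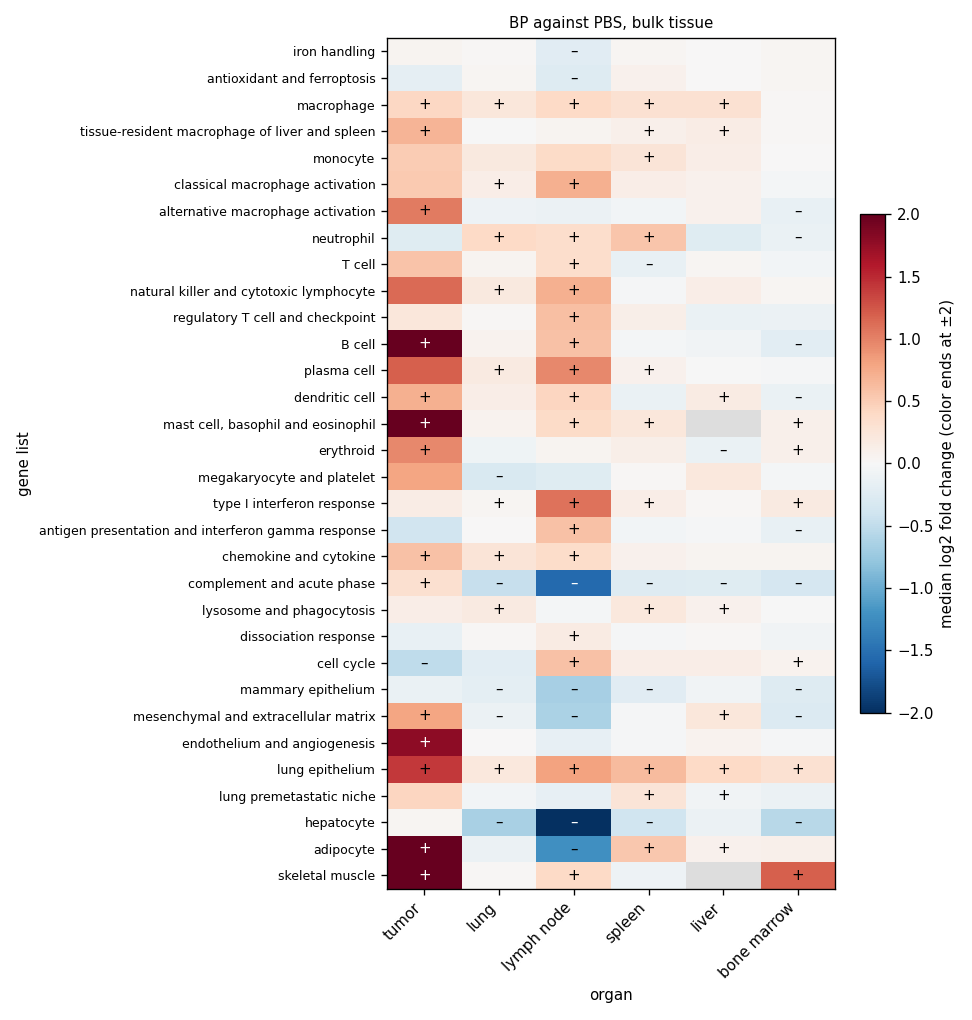
Median log2 fold change of each gene list (vertical axis) in BP against PBS bulk tissue by organ (horizontal axis), with + and – for lists called higher or lower at an adjusted p under 0.05 with the preset correlation, and gray for lists not tested. The number of called lists is 10 in liver, 14 in lung, 15 each in tumor, spleen and bone marrow and 24 in lymph node.

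Whether the effect of BP differed between organs was tested directly. In tumor Hmox1 differed from the mean of the other organs by -2.52 ± 0.28 on the log2 scale (adjusted p = 1.85e-05). Its log2 fold change was -2.21 in tumor, against 0.05 in lung, 0.20 in spleen, 0.30 in liver, 0.22 in bone marrow and 0.45 in lymph node. This difference was called without each mouse (adjusted p = 9.29e-05 to 0.00152) and with organ-specific weights and the mouse as a block in limma voom (0.0408). In total 756 genes were called for tumor, 597 higher and 159 lower, among 18613 tested. Fat and vessel genes were among the former, such as Pparg (5.415 ± 1.015, adjusted p = 0.00365), Lyve1 (3.73 ± 0.73, 0.00485) and Vwf (3.15 ± 0.63, 0.00557). The endoplasmic reticulum genes Hyou1 (-1.16, adjusted p = 0.00826) and Sec61a1 (-0.90, 0.00469), chosen after their values were seen, were lower. Each of these 5 calls was lost without PBS mouse 2 (adjusted p = 0.0513 to 0.0829). Without BP mouse 1 those of Pparg (0.197), Vwf (0.115), Hyou1 (0.101) and Sec61a1 (0.111) were lost, without BP mouse 2 those of Lyve1 (0.0636) and Hyou1 (0.0929), and without PBS mouse 3 those of Vwf (0.0629) and Sec61a1 (0.0569). Of the lists 22 were called for bone marrow, 19 for lymph node, 14 for tumor, 10 each for spleen and liver and 9 for lung. Those for tumor included endothelium (adjusted p = 2.13e-17) and adipocyte (median 5.015, 3.28e-09) higher and cell cycle (0.000114, 0.179 without PBS mouse 2) lower. Against the mean of the other organs, lymph node interferon genes were higher (median 1.04, 2.79e-08). Adipocyte (1.04e-17) and hepatocyte genes (2.83e-12), with the smallest p, were lower. For bone marrow all 22 lists called were below that mean, among them B cell genes (-0.68, 7.99e-12, 0.0566 without BP mouse 2). Of these, muscle and mast cell lists were called higher in BP marrow itself. No called list held with an estimated correlation (0.105 to 0.981). Exocrine pancreas genes, too few to test in single organs, were not called (0.659 to 0.849).

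With limma voom in place of edgeR, chosen after seeing the data, the tumor count was 234, and 355 when the mouse was added as a block. When organ-specific weights were added to both, it was 1, which was Hmox1, against 1 for spleen, 4 for liver, 7 for bone marrow and 0 for lung and lymph node. By edgeR the tumor count was 1686, 36 and 146 without PBS mice 1, 2 and 3 and 70, 385 and 1519 without BP mice 1, 2 and 3. For the other 5 organs edgeR called 0 genes, with 1446 (lymph node), 370 (liver), 234 (lung), 210 (spleen) and 208 (bone marrow) at an unadjusted p under 0.05. For lymph node the count was 116 without PBS mouse 1 and 342 without BP mouse 3.

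**Figure D4:**
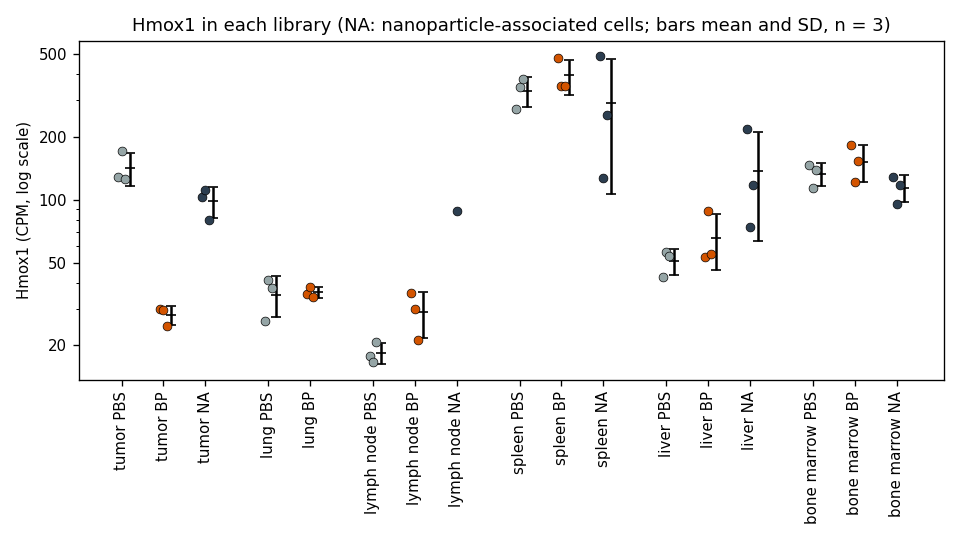
Hmox1 in CPM of the library total, on a log axis, for each group, with 1 point per library and bars for mean and SD (n = 3). Bulk tumors of BP mice lie between 24.7 and 30.0 CPM, below the 126.1 to 172.1 CPM of PBS tumors, while nanoparticle-associated tumor cells lie between 79.9 and 112.0 CPM.

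The second question was how transcripts differed between nanoparticle-associated cells and bulk tissue. No digested cells without nanoparticles were among the libraries. For all genes and lists below, digestion and magnetic separation thus cannot be told apart from the holding of nanoparticles. In liver, nanoparticle-associated cells carried endothelial, macrophage and lymphocyte transcripts at far higher levels than bulk liver. They carried hepatocyte transcripts at far lower levels. Of 24 endothelial genes 21 rose and 1 fell (median log2 fold change 4.11, adjusted p = 4.46e-17). None of the 23 list calls in these liver cells held with an estimated correlation (adjusted p = 0.24 to 0.643). The scavenger receptors of sinusoidal endothelium Stab2 went from 31.8 ± 6.46 to 716 ± 169.8 CPM and Stab1 from 38.6 ± 3.99 to 887 ± 187 CPM, and the VEGF receptor gene Kdr from 40.7 ± 7.84 to 752 ± 163 CPM. Of 30 hepatocyte genes 29 fell (median -2.55, adjusted p = 5.52e-08), such as the urea cycle gene Cps1 (ENSMUSG00000025991; chromosome 1, 67123026 to 67231259) from 2295 ± 207 to 65.0 ± 19.5 CPM and the regulator Hnf4a from 410.3 ± 25.0 to 18.5 ± 2.94 CPM. Of 22 macrophage genes 13 rose and 0 fell (adjusted p = 0.0148), led by Cd14 from 4.01 ± 0.811 to 212 ± 81.9 CPM and the mannose receptor gene Mrc1 from 53.9 ± 8.52 to 633 ± 135 CPM. B cell (16 of 16 rose, adjusted p = 0.000599), T cell (21 of 22, 0.00217), natural killer (15 of 15, 0.00157) and dendritic cell genes (18 of 20, 2.33e-06) rose.

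Immediate early and cytokine genes were among the largest increases in liver. By the naming rule, Trim69 (ENSMUSG00000033368; chromosome 2, 122160700 to 122179027), Fosb (ENSMUSG00000003545; chromosome 7, 19302696 to 19310051), Il4, Fos, Nr4a3 and Ifng led the rises. Fosb went from 0.198 ± 0.0684 to 472 ± 67.4 CPM (log2 fold change 11.15 ± 0.29, adjusted p = 1.53e-07), Fos from 0.474 ± 0.297 to 534 ± 54.9 CPM and the orphan receptor gene Nr4a3 from 0.178 ± 0.0587 to 162 ± 91.0 CPM. Trim69, whose counting is uncertain because Patl2 overlaps it, and the cytokine Il4 had 0 reads in bulk liver and were at least 380.4-fold and at least 158.4-fold higher over the groups, at 22.9 ± 4.95 and 10.96 ± 7.31 CPM. Interferon gamma (Ifng) had 3 reads in bulk and 1349 in nanoparticle-associated cells, a ratio between 225.2 and 3202 by counting error alone. Among the largest falls were those of the metabolic genes Cps1, Slc10a5, Glyctk, Gldc and Dhtkd1, with log2 fold changes of -5.14 to -4.996 and adjusted p up to 9.59e-07; the glycine cleavage gene Gldc went from 113 ± 20.7 to 3.496 ± 0.388 CPM. Of 31 dissociation genes 30 rose (median 4.98, adjusted p = 7.28e-23), as did 21 of 26 chemokine and cytokine genes (5.52e-08). Tnf went from 0.1995 ± 0.0728 to 48.9 ± 8.495 CPM. All nanoparticle-associated libraries and no bulk library had been digested.

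Iron genes went both ways in these liver cells: 9 of 32 rose and 13 fell, and the list was not called (adjusted p = 0.67). The iron-sensing signal gene Bmp6 rose from 13.9 ± 1.27 to 239.5 ± 63.5 CPM (adjusted p = 5.23e-07) and Hmox1 from 48.8 ± 13.3 to 171 ± 46.5 CPM (0.000138), while the hepatocyte hormone gene Hamp fell from 1717 ± 208 to 323 ± 104.1 CPM and the importer gene Slc39a14 from 129 ± 5.98 to 14.2 ± 4.17 CPM. Antioxidant genes were lower as a list (17 of 26 fell, adjusted p = 0.023, 0.0579 with the mouse as a block), though Slc7a11 rose from 0.159 ± 0.227 to 15.2 ± 10.2 CPM, and lysosome genes higher (16 rose and 5 fell of 30, 0.0299, 0.0618 with the block). Platelet (0.000221), mesenchymal (0.000207), antigen presentation (0.00112), interferon (0.00217), monocyte (0.00217), classical (1.02e-05) and alternative macrophage activation (0.00157), checkpoint (0.00157), neutrophil (0.00649), mast cell (0.0173) and premetastatic niche genes (0.0173) were higher as lists, and complement genes lower (0.0187). In total 9907 of 13247 genes changed, 4939 up and 4968 down, 7059 of them at least 2-fold, and groups did not overlap for 10387 (78.4%), where chance gives 10%. The block added plasma cell genes as higher (0.0117) and adipocyte genes as lower (0.0268). All 23 list calls held with each library left out. Of 36 named genes Csf1r alone lost its call, without bulk liver 3 (adjusted p = 0.0522, against 0.0112 with all libraries).

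In spleen, nanoparticle-associated cells carried more neutrophil, checkpoint and cytokine transcripts than bulk spleen and fewer transcripts of B cells, T cells and resident macrophages. Of 24 neutrophil genes 12 rose and 0 fell (median log2 fold change 1.24, adjusted p = 8.17e-06). None of the 16 list calls in these spleen cells held with an estimated correlation (adjusted p = 0.295 to 0.971). The decoy receptor Il1r2 went from 1.81 ± 0.702 to 164 ± 26.7 CPM and the receptor Trem1 from 4.10 ± 0.275 to 39.2 ± 13.01 CPM. Of 18 regulatory and checkpoint genes 12 rose (adjusted p = 1.54e-06), with Cd274, which encodes PD-L1, from 45.4 ± 6.23 to 289.6 ± 36.1 CPM and Ctla4 from 5.35 ± 2.60 to 32.25 ± 2.82 CPM. Of 17 resident macrophage genes 5 fell and 0 rose (adjusted p = 0.00989). The iron exporter gene Slc40a1 went from 489 ± 104.8 to 84.8 ± 18.0 CPM. Of 17 B cell genes 8 fell (adjusted p = 0.0193). Cr2 went from 831 ± 123 to 212 ± 23.2 CPM and Ms4a1 from 895 ± 94.6 to 249.6 ± 16.5 CPM. T cell genes were lower as a list (8 fell of 22, 0.0472) and interferon genes too (11 fell of 31, 0.0118).

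The largest rises in spleen were Acod1 (ENSMUSG00000022126; chromosome 14, 103046977 to 103056573), which makes itaconate in activated macrophages, from 0.382 ± 0.116 to 190.5 ± 63.8 CPM, the neutrophil chemokine Cxcl2 from 0.828 ± 0.401 to 319.6 ± 117 CPM, Hspa1a and Hspa1b, near-identical heat shock genes with uncertain counts, Ptgs2 of prostaglandin synthesis and the orphan receptor gene Nr4a2 from 1.03 ± 0.127 to 184 ± 29.9 CPM (log2 fold change 7.47 ± 0.205, adjusted p = 3.06e-05). The largest falls were Sectm1a, Senp8, Gdf6, Coch, Calhm2 and Exosc6, with Coch from 402 ± 123 to 44.35 ± 29.4 CPM. Exosc6 had 323 reads in bulk and 0 in nanoparticle-associated cells, at least 100.3-fold lower over the group, and its counting is uncertain because it lies within Aars. Of 31 dissociation genes 29 rose (median 3.08, adjusted p = 3.9e-44), as did 18 of 28 chemokine and cytokine genes (1.06e-06), while the stromal chemokines Cxcl13 and Ccl19 fell from 116 ± 19.85 to 17.1 ± 4.502 CPM and from 49.01 ± 10.5 to 6.28 ± 3.36 CPM. In the iron list 7 genes rose and 7 fell (adjusted p = 0.994), with ferritin heavy chain (Fth1) from 1412 ± 231 to 3080 ± 144 CPM. Antioxidant genes were higher (12 rose of 27, 0.00139). The cystine importer Slc7a11 went from 6.96 ± 1.92 to 92.4 ± 34.6 CPM. Classical (3.89e-07) and alternative macrophage activation (0.00769), premetastatic niche (4.21e-06), plasma cell (0.0121), mast cell (0.0443, 0.0539 with the mouse as a block) and endothelial lists (0.0443) were higher and the adipocyte list lower (0.0121).

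In total 6340 of 15026 genes changed in spleen (3036 up, 3304 down), 3392 at least 2-fold, and groups did not overlap for 8350 (55.6%), where chance gives 10%. The block added erythroid (adjusted p = 0.00023) and cell cycle genes (0.0268) as higher lists. The T cell, B cell, mast cell and endothelial calls were lost without single libraries: 3 without bulk 2 (0.0509 to 0.0724), 4 without bulk 3 (0.0585 to 0.233), 3 without nanoparticle-associated 1 (0.107 to 0.211), 2 without nanoparticle-associated 2 (0.0548 to 0.0669) and 1 without nanoparticle-associated 3 (0.0605). Of 36 named genes 32 held, and Gdf6 (0.0513 without nanoparticle-associated 3) and Ltf (0.0511 without bulk 2) did not, nor did Lyz2 (up to 0.109 without any library but nanoparticle-associated 1) or Cd5l (up to 0.0783 without bulk 1 or 2 or nanoparticle-associated 2 or 3).

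In tumor, nanoparticle-associated cells carried more cytokine and immediate early transcripts than bulk tumor and fewer macrophage and fat transcripts. Of 22 macrophage genes 13 fell and 0 rose (median log2 fold change -1.46, adjusted p = 3.51e-12). With an estimated correlation none of the 9 list calls in these tumor cells held (adjusted p = 0.0635 to 0.844). Lyz2 went from 594 ± 103.3 to 134 ± 19.1 CPM, Trem2 from 25.3 ± 3.33 to 5.92 ± 0.557 CPM and C1qa from 143 ± 28.02 to 51.05 ± 6.92 CPM. Of 28 mammary epithelial genes 4 rose and 0 fell, with keratin 8 (Krt8) from 1102 ± 419 to 4112 ± 514 CPM (0.0522 with the mouse as a block) and Cldn4 of tight junctions from 125 ± 95.9 to 2362 ± 822.5 CPM, though the list was not called (adjusted p = 0.433). Of 19 adipocyte genes 10 fell (median -6.89, adjusted p = 2.86e-09). Adipoq went from 404 ± 577 to 1.36 ± 0.271 CPM, where bulk tumor 1 was the fat-rich library. Chemokine and cytokine (17 of 28 rose, 4.1e-19) and classical activation genes (8 of 16, 2.86e-09) were higher, as were 25 of 31 dissociation genes (median 2.60, 2.72e-53).

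The largest rises in tumor were Cxcl2 (ENSMUSG00000058427; chromosome 5, 90903871 to 90905938) from 0.323 ± 0.307 to 338 ± 126 CPM (log2 fold change 9.915 ± 0.805, adjusted p = 0.0039), Fosb from 1.09 ± 0.601 to 769 ± 209.9 CPM, the AP-1 gene Fosl1, the granulocyte growth factor Csf3 from 0.431 ± 0.222 to 163 ± 71.9 CPM, the cytokine Lif from 3.99 ± 1.46 to 849.5 ± 295 CPM and Acod1. The largest falls were fat genes, Retn, Adrb3, Ucp3, Cox8b (adjusted p = 0.048, 0.0879 with the block), Cfd and Hcar1. Cfd went from 1965 ± 2942 to 6.255 ± 2.48 CPM, and Adrb3, Hcar1 and Ucp3 had 3, 2 and 1 reads in nanoparticle-associated cells against 1611, 546 and 524 in bulk, with ratios between 0.0003867 and 0.005495, 0.000446 and 0.0134, and 4.861e-05 and 0.01076 by counting error. In the iron list 3 genes rose and 2 fell (adjusted p = 0.898): Hmox1 with a log2 fold change of 1.81 ± 0.28, the heme exporter gene Flvcr1 from 15.85 ± 1.15 to 72.9 ± 12.0 CPM and Slc11a2 from 30.5 ± 4.84 to 56.0 ± 4.52 CPM against Hp from 280.1 ± 325 to 21.2 ± 4.63 CPM and Heph from 9.14 ± 7.61 to 0.972 ± 0.543 CPM, of which Slc11a2 (0.0589), Hp (0.088) and Heph (0.0587) were not called with the block. In the antioxidant list 5 of 27 rose, such as Srxn1 from 29.4 ± 3.6 to 129 ± 62.1 CPM, and the list was not called (0.267). B cell (0.00481), antigen presentation (0.00187) and resident macrophage genes (0.0268) were lower as lists and premetastatic niche genes higher (4.86e-05). The block added monocyte (0.0157), dendritic cell (0.0435) and mast cell genes (0.00047) as lower lists.

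In total 1321 of 14615 genes changed in tumor, 858 up and 463 down (65% up), 1154 at least 2-fold, and groups did not overlap for 5654 (38.7%), where chance gives 10%. The mouse as a block gave 625, DESeq2 3303 with 48.7% up, no filter 1430 with 52.3% up, and the spread over 48 libraries 5770 with 41.2% up. The count was 20, 51 and 211 without nanoparticle-associated libraries 1, 2 and 3, of which 0, 0 and 7 were falls, and 426, 265 and 1935 without bulk tumors 1, 2 and 3. Of the 35 named genes 8 were called with each library left out (Cxcl2, Fosb, Csf3, Lif, Cxcl1, Tnf, Ccl3 and Fos), and the others reached adjusted p of 0.0652 to 0.179; 8, 10 and 19 stayed called without nanoparticle-associated 1, 2 and 3, and 25, 17 and 34 without bulk 1, 2 and 3. Of 9 list calls the resident macrophage list was lost without bulk 1 (0.151) or 2 (0.128) and antigen presentation without bulk 1 (0.14).

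In bone marrow, nanoparticle-associated cells carried more immediate early and inflammatory transcripts than bulk marrow and fewer stromal ones. Of 31 dissociation genes 24 rose (median log2 fold change 1.83, adjusted p = 1.76e-100). Fos went from 7.56 ± 3.17 to 175 ± 9.76 CPM and Jun from 7.82 ± 0.998 to 137 ± 3.755 CPM. Chemokine and cytokine genes were higher (11 rose and 2 fell of 21, 1.98e-16). Ccl3 went from 1.26 ± 0.2205 to 19.1 ± 2.33 CPM and Il1b from 39.1 ± 7.71 to 101.3 ± 6.55 CPM. The dissociation and the chemokine and cytokine list in bone marrow were the only calls of the 10 comparisons that held with an estimated correlation, both at adjusted p = 0.015. Mesenchymal genes were lower (7 fell and 1 rose of 30, 0.00532). Col6a1 went from 10.2 ± 1.155 to 3.34 ± 0.315 CPM. The largest rises were Fosb from 0.365 ± 0.170 to 142 ± 18.8 CPM, Cxcl2, Nr4a3, Nr4a2, Ptgs2 and Acod1, and the largest falls Cxcl12 (ENSMUSG00000061353; chromosome 6, 117168535 to 117181367), a niche chemokine of marrow stroma, from 210.2 ± 32.0 to 50.6 ± 19.6 CPM (log2 fold change -2.06 ± 0.29, adjusted p = 0.00624), the leptin receptor gene Lepr from 18.5 ± 3.55 to 4.11 ± 1.75 CPM, Ltbp2, Cxcl14, Esm1 and Igfbp5. The monocyte receptor Cd14 rose from 29.5 ± 4.64 to 554.5 ± 80.9 CPM, the coagulation-related gene Thbs1 from 200.2 ± 10.35 to 983 ± 196 CPM and Slc7a11 from 4.18 ± 0.0424 to 63.5 ± 11.7 CPM. Of 31 iron genes 1 rose (Id1, from 14.0 ± 1.91 to 28.5 ± 3.19 CPM) and 1 fell (Slc40a1, from 191 ± 2.93 to 136 ± 12.7 CPM), and the list was not called (0.533).

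Classical activation (5.87e-08), antioxidant (6.82e-05), neutrophil (0.00252), premetastatic niche (0.00252), alternative activation (0.0175), endothelial (0.031, 0.0822 with the mouse as a block) and plasma cell lists (0.0446) were higher in nanoparticle-associated marrow cells, and B cell (0.00382) and interferon lists (0.00734) lower. With an estimated correlation these and the mesenchymal list had adjusted p = 0.173 to 0.761. In total 1044 of 13573 genes changed (651 up, 393 down), 436 at least 2-fold, and groups did not overlap for 4146 (30.5%), where chance gives 10%. The block gave 2719 calls, 1042 of them shared, and the count was 1899, 367 and 528 without nanoparticle-associated libraries 1, 2 and 3 and 320, 289 and 468 without bulk 1, 2 and 3. Of 29 named genes 25 held with each library left out, Esm1 (0.0538 without nanoparticle-associated 2), Col1a2 (up to 0.076) and Ncr1 (up to 0.0809, both without bulk 1 or nanoparticle-associated 2 or 3) and Slc40a1 (up to 0.112 without any library but nanoparticle-associated 1) did not. The plasma cell, alternative activation, interferon, endothelial and B cell calls were lost without single libraries: 1 without bulk 1 (0.0758), 3 without bulk 2 (0.0567 to 0.167), 1 without bulk 3 (0.0687), 2 without nanoparticle-associated 1 (0.0533 to 0.126), 2 without nanoparticle-associated 2 (0.0793 to 0.0811) and 2 without nanoparticle-associated 3 (0.0665).

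**Figure D5:**
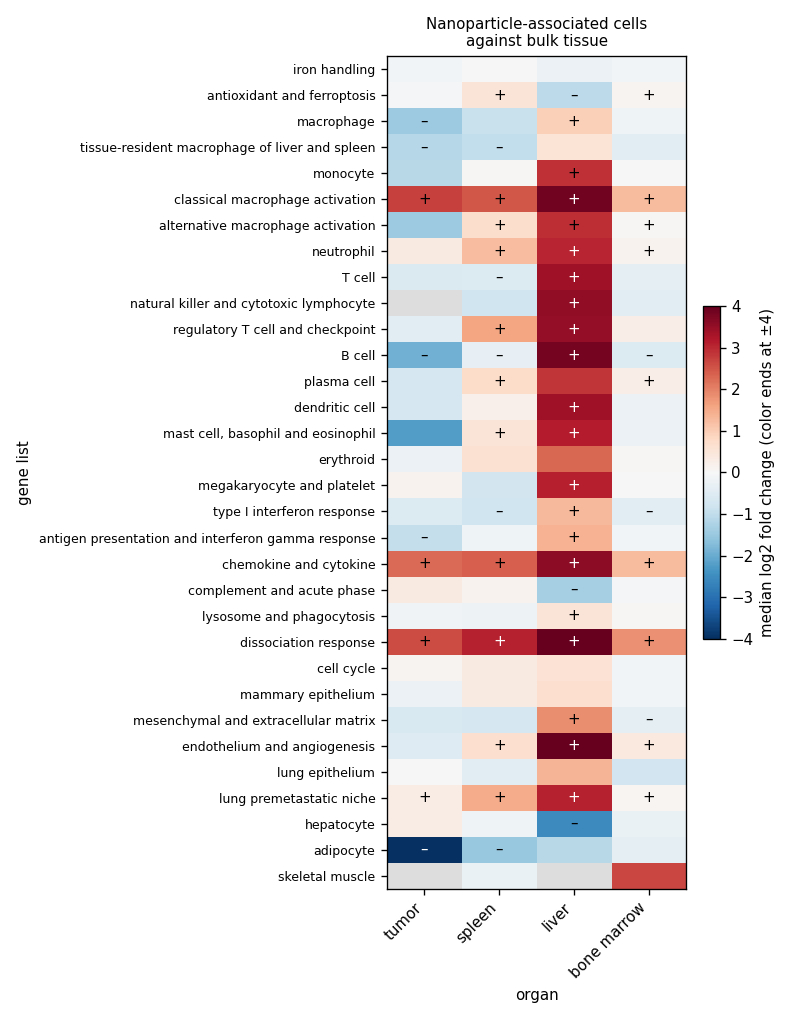
Median log2 fold change of each gene list (vertical axis) in nanoparticle-associated cells against BP bulk tissue by organ (horizontal axis), with + and – for lists called higher or lower at an adjusted p under 0.05 with the preset correlation, and gray for lists not tested. The dissociation response is called higher in all 4 organs, with medians of 1.83 in bone marrow, 2.60 in tumor, 3.08 in spleen and 4.98 in liver.

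The single lymph node library of nanoparticle-associated cells had no replicate and no test, and was set beside the bulk node of the same mouse over 15691 genes. All 31 dissociation genes were higher in it (median log2 difference 1.93, percentile 100 among 10000 random lists of matched expression, a description of these 2 libraries), with Fosb from 1.41 to 379 CPM. The cytokine gene Il6 went from 0.761 to 86.75 CPM. Mast cell genes were higher (median 1.59, percentile 100), with Mcpt4 from 43.5 to 124 CPM, as were mammary genes (1.71, percentile 100), with Krt8 from 5.00 to 67.7 CPM, and iron genes (0.49, percentile 99.36), with Hmox1 from 30.6 to 86.65 CPM. T cell (-0.76, percentile 0), B cell (-0.66, percentile 0.23) and cell cycle genes (-1.02, percentile 0) were lower, with Ms4a1 from 266 to 127 CPM. Hepatocyte genes stood at a median of 4.29 (percentile 100) and lung epithelium genes at -1.97 (percentile 0), and these libraries belong to different sets of liver and lung transcripts.

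Differences between organs in this enrichment were tested directly over 17281 genes. They depend on the level in bulk tissue as well as on that in nanoparticle-associated cells. Each organ was set against the mean of the others, so a call does not place it above or below each single organ. All 19 lists called for tumor were lower than the mean of the other 3 organs, among them dendritic cell (adjusted p = 2.61e-10) and endothelial genes (1.03e-08). Macrophage genes were another (adjusted p = 1.16e-10, 0.264 with an estimated correlation). Their member Cd14 stood at -4.30 ± 0.31 on the log2 scale (adjusted p = 1.32e-07) and Lyz2 at -2.14 ± 0.30 (6.65e-05). Gpnmb of the lysosome list was lower for tumor as well (-4.76 ± 1.04, 0.00262, 0.0735 without mouse 3). For liver, endothelial (1.09e-08), dendritic cell (2.82e-09) and dissociation genes (7.61e-09) were higher, with Stab2 at 3.78 ± 0.48 (2.19e-06), and so was Bmp6 (4.26 ± 0.38, 2.89e-08). For spleen, antioxidant genes were higher (3.96e-05) and Slc40a1 lower (-2.03 ± 0.30, 0.000144). For bone marrow, dissociation genes were higher than in bulk but by less than in the other organs (-1.52, 1.59e-21). Hmox1 was higher for tumor (1.45 ± 0.38, 0.00866) and liver (1.36 ± 0.38, 0.00465) and lower for spleen (-1.33 ± 0.37, 0.0178) and bone marrow (-1.48 ± 0.38, 0.0132). Each of these Hmox1 calls was lost without single mice: for tumor without mouse 2 (0.0625) or 3 (0.107), for liver without 3 (0.0897), for spleen without 2 (0.0748) or 3 (0.199), and for bone marrow without 1 (0.0776) or 3 (0.199). With organ-specific weights and the mouse as a block in limma voom the one for tumor was lost (0.125). The other genes and lists named here were called without each mouse. The dissociation list for bone marrow held with an estimated correlation (0.0201) and no other list did, of 19 called for tumor, 6 for spleen, 20 for liver and 15 for bone marrow. The numbers of genes called were 4119 for tumor, 3146 for spleen, 9272 for liver and 2592 for bone marrow. Without mice 1, 2 and 3 they were 1656, 2421 and 2243 for tumor, 1470, 1398 and 588 for spleen, and 1263, 491 and 161 for bone marrow, and with those weights and the block 1423 for tumor and 4055 for bone marrow.

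The premetastatic niche list in BP livers was the only called list of the 10 comparisons whose median differed in sign from its mean and its test. Among lists that were not called, the median, mean and test differed in sign in BP tumors for neutrophil and mammary genes. They did in lung for iron, antioxidant, alternative activation, checkpoint, erythroid, antigen presentation, dissociation, endothelial and adipocyte genes, in lymph node for resident macrophage, lysosome and erythroid genes, and in spleen for B cell, erythroid, platelet and dissociation genes. In BP livers they did for iron, B cell, plasma cell, chemokine and dissociation genes, and in bone marrow for iron, resident macrophage, natural killer, platelet and endothelial genes. In nanoparticle-associated cells they did for antioxidant, neutrophil, checkpoint, complement, mammary, platelet, lung epithelium and hepatocyte genes of tumor, iron and complement genes of spleen, and macrophage, monocyte, mast cell and erythroid genes of bone marrow.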

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

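The tests of carry-over of liver and tumor transcripts, the second set of tumor genes and both tests of the dissociation response were chosen after the result was seen, and the counts of other splits before.

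The effect of BP on tumor differed from the mean of the other organs for 756 genes, by a direct test. Of the 10 splits of the 6 mice 2 gave as many, the real one included, and the highest other gave 2798; 10 splits are too few for a share under 0.05. That other split (BP mice 1 and 2 and PBS mouse 1 against the rest) gave 1517 for lymph node, where the real split gave 0. In organs tested alone it gave 1169 in lymph node and 0 in tumor, and the real split 0 in both. The other split follows no labelled batch, and the cause of its calls was not tested. For lung, liver, spleen and bone marrow the real split gave 0 and the highest others 1, 1, 0 and 0, so all 10 gave as many.

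The enrichment in nanoparticle-associated cells differed between organs for 4119 genes in tumor, 3146 in spleen, 9272 in liver and 2592 in bone marrow, again by a direct test. Among 21 drawn splits of the libraries within organs, the highest others gave 886, 429, 7440 and 187. In each organ 1 of 21, the real one, gave as many. The draws mixed nanoparticle-associated with bulk libraries in all organs at once, which also breaks up the change that the organs share. They therefore cannot decide whether the differences between organs arose by chance.

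The lymph node library of nanoparticle-associated cells stood in no tested comparison, and its dissociation genes lay above the bulk node of the same mouse by a median of 1.931 on the log2 scale.

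Within single organs 10 splits of 6 libraries are too few for a share under 0.05. For genes, BP against PBS gave 3 in liver (highest other 1, so 1 split gave as many), and 0 in tumor, lung, lymph node, spleen and bone marrow (highest others 0, 1, 1169, 0 and 2, so all 10 gave as many). Nanoparticle-associated cells against bulk gave 1321 in tumor, 6340 in spleen and 9907 in liver, with 0 in the highest other, and 1044 in bone marrow with 10; the splits that part all 3 pairs, as the real one does, gave 0 apart from it. For gene lists, the real number and the highest other were 15 and 23 in tumor (6 splits gave as many), 14 and 25 in lung (6), 24 and 22 in lymph node (1), 15 and 22 in spleen (6), 10 and 14 in liver (4) and 15 and 19 in bone marrow (2) for BP against PBS. They were 9 and 21 in tumor (9), 16 and 21 in spleen (7), 23 and 26 in liver (4) and 12 and 15 in bone marrow (5) for nanoparticle-associated cells. In each comparison except lymph node, at least 1 split that mixes the groups thus called as many lists. In lymph node the highest other, at 22, lay near the real 24.

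Liver transcripts in libraries of other organs were weighed first. Liver tissue taken along at dissection stays open, since 7 of 24 bulk libraries correlated most with the liver of the same mouse, where chance gives 4. Reads carried over between libraries stay open as well. The SD of the log2 ratio to liver over 8 liver genes had a median of 0.281 over these libraries (0.146 to 1.104), and a low SD is what either source would give. It was highest in the lymph node of BP mouse 2 (1.088) and the bone marrow of BP mouse 3 (1.104). No biological explanation was tested.

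Tumor transcripts in the lung of PBS mouse 2 were weighed second. Over 43 tumor genes the share of the tumor level was 1.36 times the highest of 17 other lung, spleen and bone marrow libraries, which decides nothing, as the other lungs held 5.93 to 9.2% and the spleens and bone marrows 0.125 to 0.44%. The tumor of the same mouse ranked 1 of 6 by correlation (0.561, next 0.266). Over 13 genes chosen as near absent in the other lungs, this lung held 3.98% of the tumor level. This was 13.6 times the highest of 18 spleen, bone marrow and liver libraries, which were not used in that choice, and argues against reads carried over into libraries of all organs alike. Bulk lymph nodes held 0.374 to 10.1%. The same tumor ranked 1 again (0.844, next 0.359). Tumor cells of that mouse in its lung could be the source, carry-over into single libraries stays open, and mammary tissue taken along was not tested.

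The dissociation response in nanoparticle-associated cells was weighed last. Of its 31 genes 20 rose in all 4 organs, and all nanoparticle-associated libraries were digested while no bulk library was. Contact of the cells with nanoparticles may contribute too, and 0 of the genes passed the edgeR threshold in any organ of BP against PBS tissue. The list itself was called higher in lymph nodes of BP mice (adjusted p = 0.0144), though not with an estimated correlation (0.449) or without 4 of the 6 libraries in turn (up to 0.295), and in no other organ. The design confounds the 2 explanations, so they cannot be told apart.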

How the results depend on the processing

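List tests without single libraries, fits within 1 library set, without doubtful libraries or without mitochondrial genes, organ-specific weights, limma voom without a block and interaction fits without single mice were chosen after seeing the data. Of the counts of genes, 128 under settings fixed beforehand and 50 under those added later stayed within 1.5 times the value reported, and 32 and 25 moved beyond it. Of the gene list tests 301 of the former and 910 of the latter kept direction and side of the threshold, 158 and 177 lost the call and 35 of the latter turned. Of single genes 2873 and 202 kept both, 149 and 26 lost the call, 43 and 2 gained it and 2 of the former turned. The cause was not tested unless stated.

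For BP against PBS, DESeq2 gave 138 genes in tumor, 11 in lymph node, 37 in liver and 4 in bone marrow, where edgeR gave 0, 0, 3 and 0. Without a filter liver gave 49 and bone marrow 27. With the spread over all 48 libraries tumor gave 1482 and lymph node 1, and within 1 library set lymph node gave 46, with 1 BP library left whose spread is assumed to be that of the others. Leaving out 1 library gave 0 to 1 in lung, 1 to 9 in liver and 0 to 1 in bone marrow. For nanoparticle-associated cells, DESeq2 gave 3303 in tumor and the spread over all 48 libraries 5770 in tumor and 373 in bone marrow. The replicate block gave 625 in tumor and 2719 in bone marrow. Leaving out 1 library gave 20 to 1935 in tumor and 289 to 1899 in bone marrow. In nanoparticle-associated liver cells the median of all genes was 0.134 with the spread over 48 libraries and 0.32 without a filter, against 0.009. There the replicate block gave 9754 genes, 9629 of them among the 9907. Of the named genes and gene lists in nanoparticle-associated cells, it changed no call beyond those given in the report.

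For differences between organs under BP, limma voom in place of edgeR gave 234 for tumor, and 355 with the replicate block, whose consensus correlation was 0.058. Organ-specific weights with the mouse as a block in limma voom gave 1 for tumor, 1 for spleen, 4 for liver and 7 for bone marrow under BP, and 1423 for tumor and 4055 for bone marrow in nanoparticle-associated cells. Leaving out 1 mouse gave 36 to 1686 for tumor and 0 to 342 for lymph node under BP, and 1656 to 2421 for tumor, 588 to 1470 for spleen and 161 to 1263 for bone marrow in nanoparticle-associated cells.

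Some directions turned without single libraries, and the ranges in this paragraph are over the 6 libraries left out in turn, of log2 fold changes for genes and of adjusted p for lists. In tumor, without BP 2, they were Acta1, BP against PBS, tumor (-1.30 to 9.08), Mylpf, BP against PBS, tumor (-0.24 to 8.88), skeletal muscle (3.23e-05 to 0.544) and erythroid (0.000322 to 0.577), and without BP 1 cell cycle (9.45e-08 to 0.661). In lung, without PBS 1, they were macrophage (7e-07 to 0.534), neutrophil (1.31e-05 to 0.219, turned at 0.0435), natural killer and cytotoxic lymphocyte (6.53e-06 to 0.174, turned at 0.0169), plasma cell (3.83e-06 to 0.514), mesenchymal and extracellular matrix (0.00162 to 0.972) and type I interferon response (0.000108 to 0.726, the last without BP 2, and 0.665 without PBS 1). In lymph node, without BP 2, it was T cell (1.45e-05 to 0.274). In spleen, without BP 1, they were T cell (4.97e-14 to 0.137), plasma cell (2.17e-05 to 0.964), lung premetastatic niche (7.15e-07 to 0.964) and tissue-resident macrophage of liver and spleen (7.25e-05 to 0.932, and 0.901 without PBS 1). Without BP 3 they were complement and acute phase (3.25e-07 to 0.12) and hepatocyte (2.82e-27 to 0.697). In bone marrow they were neutrophil without PBS 1 (4.56e-05 to 0.584), B cell without PBS 2 (2.64e-06 to 0.344) and BP 2 (0.00967), erythroid without BP 3 (0.446, range 1.95e-18 to 0.555) and antigen presentation and interferon gamma response without PBS 3 (3.88e-16 to 0.837).

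Within 1 library set, lists that turned were lung epithelium in tumor (0.974), spleen (0.184) and bone marrow (0.237), complement and acute phase in spleen (0.287), neutrophil (0.946) and erythroid (0.124) in bone marrow, and T cell (0.646) and dissociation response (0.347) in lymph node. For lymph node this leaves 1 BP library. With PBS lungs 1 and 2 left out, which leaves 1 PBS library assumed to vary like the others, they were macrophage (0.381), natural killer and cytotoxic lymphocyte (0.102), plasma cell (0.13) and type I interferon response (0.00553).

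BP and PBS mice share only a number. With the replicate block liver gave 3 genes, 2 of them shared with the 3 of the report, as Vcam1, BP against PBS, liver, had an adjusted p of 0.0658, and the other 5 organs gave 0. Libraries that correlated best with the one of their own number were 0 of 6 in tumor and lung, 3 in lymph node and bone marrow and 2 in spleen and liver. Depth limited genes at 0 reads to 0.152 to 0.32 CPM.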

Other observations

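The settings that left out mice in the fits across organs were chosen after the result was seen. The enrichment of several inflammatory genes in nanoparticle-associated cells was higher in liver than the mean of the other organs. Enrichment is the change against the bulk tissue of the same organ, so it depends on the bulk level too. It does not rank the organs by the level in these cells. Fos was 4.98 ± 0.44 above the mean of the other organs on the log2 scale there (adjusted p = 2.33e-08) and below it in tumor (-2.025 ± 0.37, 0.000647) and bone marrow (-2.33 ± 0.38, 0.00072). The cytokine gene Tnf was above in liver (4.74 ± 0.495, 1.85e-07) and below in bone marrow (-3.97 ± 0.40, 1.28e-05), where Il6 was below as well (-3.44 ± 0.95, 0.0199, 0.0624 and 0.337 without mice 2 and 3). The lipopolysaccharide receptor gene Cd14 was above in liver (2.19 ± 0.305, 6.3e-06) and spleen (1.77 ± 0.30, 0.000483).

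The growth factor receptor gene Csf1r of macrophages was above the mean of the other organs in liver (1.39 ± 0.34, 0.00179) and below it in tumor (-1.43 ± 0.34, 0.00496, 0.0975 without mouse 3). Gpnmb was above in liver (2.83 ± 0.94, 0.0156, 0.129 and 0.0898 without mice 1 and 3). Keratin 8 (Krt8) went the other way, above in tumor (1.42 ± 0.29, 0.00167) and below in liver (-1.60 ± 0.29, 0.000128). Lists of monocyte (adjusted p = 8.37e-05), T cell (3.48e-07) and B cell genes (3.48e-07) were above the mean of the other organs in liver and below it in tumor (6.08e-07, 2.74e-05 and 2.76e-05). The other calls given here held without each mouse, and no list did with an estimated correlation.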
